A study of Mus musculus with 17 samples.

How the data were processed

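Polyadenylated RNA from the hippocampus of 17 adult mice was sequenced by the authors as paired reads of 150 bases with a strand-specific kit, 1 library per mouse. Per the labels, 6 mice were WT (C57BL/6J), 6 carried the Dp(16)1Yey duplication of chromosome 16 (Dp16), and 5 carried the duplication with the dosage of the interferon receptor genes normalized (Dp16_2xIFNRs). The whole identifier differs for every mouse, so every library was taken as a biological replicate. Its second part is shared by 5 pairs of mice of different groups, and the labels do not say what it stands for.

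Per the submitters' processing notes, the tools were bcl2fastq, FastQC 0.11.5, HISAT2 2.1.0, SAMtools 1.5 and HTSeq 0.6.1, and the genome build was GRCm38. The authors deposited raw counts per gene for each library. The authors also deposited RPKM (reads per kilobase and per megaread) for the same libraries, and these were recomputed from the counts as a check. Solved for length, count, library total and RPKM gave 1 implied length per gene over all libraries, for 35644 genes, with a largest relative spread of 6.41e-15. Names of the deposited tables give GENCODE release 24, and gene positions were taken here from GENCODE release 21, on the same build. The strand setting of the counting and the definition of gene length for RPKM are not stated. Values of genes that overlap another gene, of antisense genes, and of near-identical families (histone, Gbp, H2, C4 and lysozyme genes) are therefore less certain than the rest.

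Depth was similar between groups. Total counts per library were 30.4 to 32.9 M (M, mega) in WT, 30.4 to 33.1 M in Dp16 and 30.7 to 31.6 M in Dp16_2xIFNRs. The common biological coefficient of variation between mice was 14.1%, and the counting error per library was smaller than that in 14566 of the 18983 tested genes. Intervals from counts cover counting error only, since reads without molecular identifiers are not independent molecules.

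Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, which left 18983 genes, 122 in the duplicated segment and 18861 outside it. The libraries were scaled by TMM, and a quasi-likelihood model with genotype and sex was fitted to all 17 libraries, with 13 residual degrees of freedom. A gene was called when its Benjamini-Hochberg adjusted p over all tested genes was under 0.05. CPM are counts per M counts of the TMM-scaled library size, and log2 CPM used a prior count of 2. The segment was every gene of the tables with a position on chromosome 16 from Lipi to Zbtb21 (75540514 to 97962622), 384 genes. Of the 55385 identifiers, 241 had no position and were counted as outside the segment. The dosage of the segment was summarised over its 101 genes with a mean of at least 1 CPM, as a median log2 fold change, and per mouse with a two-sided exact permutation test. Departure from the copy ratio of 1.5 was tested in edgeR with an offset and adjusted over the segment genes alone.

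Fixed lists of genes (47 lists, 1173 entries) were compared with all other genes by camera in limma 3.58.1 with a preset correlation of 0.01 between genes, adjusted over the lists of a comparison by Benjamini-Hochberg. Some genes stand in several lists, such as C4b (complement, reactive astrocytes) and Gbp2 (interferon gamma response, reactive astrocytes). Segment genes were taken out of each list but that of the receptors, and at least 3 tested members were required. Beside it stand camera with an estimated correlation, fry, and a two-sided exact permutation test of the mean log2 level per mouse. The groups, models, gene lists, alternatives and the rule for named genes were fixed before the data were examined.

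Genes were named by this rule. The 4 receptor genes and 15 known genes of the segment were named in every case, with the 3 highest and 3 lowest fold changes of the segment. Outside it, the 10 largest rises and 10 largest falls per comparison were named among called genes with at least 1 CPM and the same direction in both sexes. Genes with only a clone or predicted name were counted and not named. From each list, up to 4 members were named. Genes next to the receptor cluster are an exception, chosen after their values were seen.

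The alternatives fixed beforehand were DESeq2 1.42.0 (size factors, and its own test), TMM without the segment genes, limma-voom, no filter, a filter of 1 CPM in 5 libraries, no covariate, age, the identifier series, 1 surrogate variable (sva 3.50.0), a replicate block, only the 2 groups compared, a threshold of 0.1, limma-trend on the deposited RPKM with 0.1 or 1 added, and leaving out each library in turn. Added alternatives were chosen after seeing the data: the choroid plexus level as a covariate, the slope of expression on gene length as a covariate, both of them together, leaving out the 3 libraries lowest in choroid plexus markers, and limma-voom with the second part of the identifier as a random block (consensus correlation -0.0148). The identifier series is the leading digit of the second part of the identifier, and the labels do not give its meaning. Dp16 replicates 2 and 4 had a value that no other mouse had. With this covariate the Dp16 comparisons therefore rest on the remaining Dp16 mice. All columns of the deposited tables belonged to the 17 libraries.

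The steps were tested on simulated data of the 18983 genes. In each, 200 genes outside the segment with at least 1 CPM were changed, so the shares recovered apply to such genes. Segment genes were also raised 1.5-fold in both duplication groups. In the simulation of Dp16, 3 lists were shifted as well. Segment genes and members of shifted lists were not counted among the further calls. In Dp16 against WT, 49.3%, 74.6% and 93.9% of genes changed 1.25-fold, 1.5-fold and 2-fold were recovered, with 7 further calls. In Dp16_2xIFNRs against WT the shares were 43.3%, 73.1% and 93.9%, with 9 further calls. In Dp16_2xIFNRs against Dp16 they were 29.9%, 70.1% and 87.9%, with 5 further calls. The test of sex by genotype recovered 19.4% at 1.5-fold and 54.5% at 2-fold, with 5 further calls. All 3 lists shifted by 0.2 on the log2 scale were called, and 0 of 43 unshifted lists were. The simulated genes were drawn independently of each other. The count of 0 therefore does not carry over to lists whose members vary together between mice. A simulated share of 50 percent came out as 50.4 percent.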

Results

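RNA of the hippocampus was counted in 17 mice aged 17.1 to 18.0 weeks. The groups were WT (n = 6, 3 females and 3 males), Dp16 (n = 6, 3 females and 3 males) and Dp16_2xIFNRs (n = 5, 3 females and 2 males). Dp16 mice, a model of Down syndrome, carry 3 copies of a segment of chromosome 16 whose genes have their counterparts on human chromosome 21. That segment holds the genes of 4 interferon receptor chains, which Dp16_2xIFNRs mice carry in the normal number. Library totals lay between 30.4 and 33.1 M counts (M, mega). Libraries with the same replicate number in different groups were not more alike than others (mean correlation of their deviations 0.00735 over 16 pairs, against 0.00390 for other pairs). The second part of the mouse identifier takes 12 values, and 5 pairs of mice of different groups share one. The labels do not give its meaning, and the deviations of these pairs had a mean correlation of -0.105 (-0.431 to 0.358), against 0.0105 for other pairs across groups. Xist reached at most 0.445 CPM in the 8 males, whose Ddx3y was at 63.5 to 79.8 CPM, and Ddx3y had no counts in the 9 females, so the labelled sexes fit the counts.

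The first comparison asked whether the receptor genes had the dosage that the labels give. Ifnar1 and Ifnar2, the chains of the type I interferon receptor, and Ifngr2, a chain of the interferon gamma receptor, were about 1.5-fold higher in Dp16 than in WT and lower again in Dp16_2xIFNRs. Il10rb, a chain shared by the receptors of interleukin 10 and of type III interferons, was higher in Dp16 than in WT as well. The genes lie together on chromosome 16 (GRCm38): Ifnar2 (ENSMUSG00000022971.18) at 91372783 to 91405589, Il10rb (ENSMUSG00000022969.13) at 91406164 to 91425834, Ifnar1 (ENSMUSG00000022967.13) at 91485238 to 91507441 and Ifngr2 (ENSMUSG00000022965.8) at 91547072 to 91565623. Ifnar1 stood at 41.3 ± 3.64 CPM (SD, n = 6) in WT, 64.6 ± 2.75 CPM (n = 6) in Dp16 and 46.2 ± 2.08 CPM (n = 5) in Dp16_2xIFNRs. Ifnar2 stood at 17.9 ± 2.22, 27.3 ± 2.06 and 17.7 ± 1.46 CPM in the same order. Ifngr2 stood at 52.5 ± 4.37, 82.6 ± 7.11 and 51.7 ± 1.99 CPM, and Il10rb at 8.10 ± 0.817, 11.7 ± 1.72 and 7.98 ± 0.652 CPM.

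In Dp16 against WT the log2 fold changes were 0.65 ± 0.05 (SE) for Ifnar1 (edgeR adjusted p = 8.81e-07), 0.61 ± 0.08 for Ifnar2 (edgeR adjusted p = 0.000153) and 0.65 ± 0.06 for Ifngr2 (edgeR adjusted p = 3.88e-06). Il10rb rose by 0.54 ± 0.10 (edgeR adjusted p = 0.0146). That call was lost without Dp16 replicate 5 (edgeR adjusted p = 0.0518) and with the identifier series as a covariate (edgeR adjusted p = 0.120; 0.000134 to 0.120 over 19 alternatives). In Dp16_2xIFNRs against Dp16, Ifnar1 fell by 0.49 ± 0.06 (edgeR adjusted p = 0.000841), Ifnar2 by 0.63 ± 0.08 (edgeR adjusted p = 0.00329) and Ifngr2 by 0.68 ± 0.07 (edgeR adjusted p = 0.000136). With the identifier series as a covariate, Ifnar2 was no longer called there (edgeR adjusted p = 0.0752; 3.51e-09 to 0.0752 over 19 alternatives). That covariate leaves fewer Dp16 mice to compare, since some hold a value found in no other group. Il10rb had a log2 fold change of -0.56 ± 0.11 that did not pass over all genes (edgeR adjusted p = 0.277; 0.00251 to 0.742 over 19 alternatives; unadjusted p = 7.1e-05). It was called by DESeq2, and by edgeR without Dp16 replicate 6, whose 8.47 CPM lay among the WT values. In Dp16_2xIFNRs against WT, edgeR called 0 of the 4 receptors, with 1 at an unadjusted p under 0.05 and 0 called by DESeq2 or limma-voom. The log2 fold changes there were 0.16 for Ifnar1 (edgeR adjusted p = 0.181) and -0.02 for each of Ifnar2, Ifngr2 and Il10rb, and without WT replicate 2 edgeR called 1 of the 4. The mean receptor level per mouse separated Dp16 from WT and from Dp16_2xIFNRs (exact permutation p = 0.00216 in both cases, the smallest these groups allow, and 0.102 adjusted over the lists). Of the genes beside the cluster, 2 that were chosen after their values were seen stayed near the duplicated level: Tmem50b had log2 fold changes against WT of 0.61 in Dp16 and 0.52 in Dp16_2xIFNRs, and Gart of 0.61 and 0.57. Olig1 and Olig2, at lower positions than the cluster, were at 0.35 and 0.30 in Dp16 against WT.

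**Figure D1:**
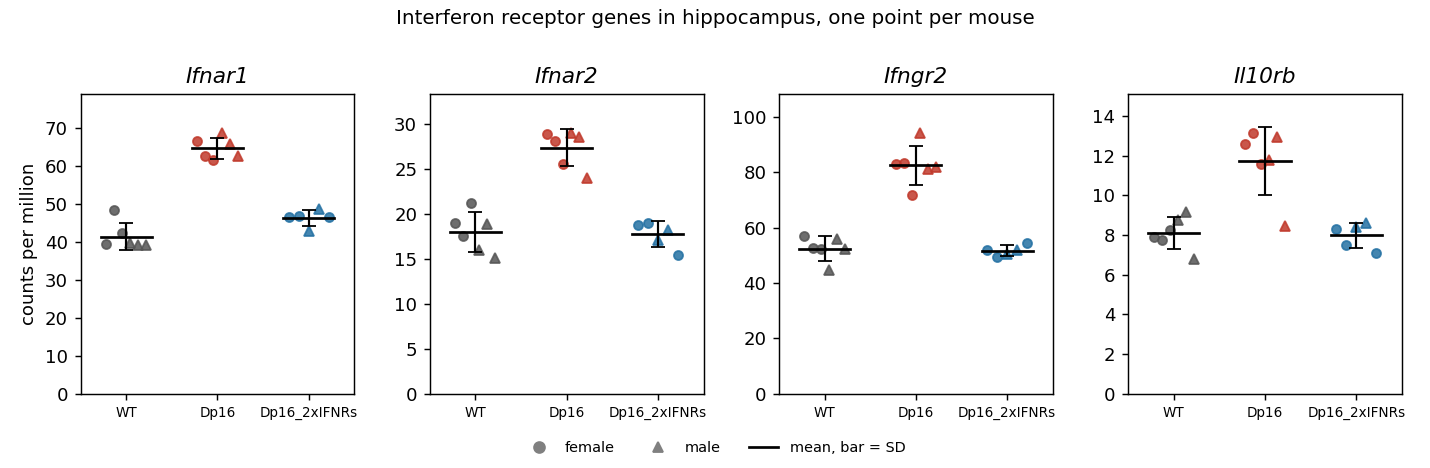
Expression of Ifnar1, Ifnar2, Ifngr2 and Il10rb in CPM for each mouse of the WT, Dp16 and Dp16_2xIFNRs groups (circles females, triangles males, black line the mean, bar 1 SD). All Dp16 mice lie above all mice of the other groups for Ifnar1, Ifnar2 and Ifngr2, and Dp16 replicate 6 lies low for Il10rb at 8.47 CPM.

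The second comparison asked how far the segment's genes followed their copy number in Dp16 mice. The triplicated genes rose together, by a median of 1.48-fold. App, the amyloid precursor protein, Dyrk1a, a protein kinase, Sod1, the cytosolic superoxide dismutase, and Rcan1, an inhibitor of calcineurin, all rose in Dp16 and in Dp16_2xIFNRs. Synj1, a lipid phosphatase of vesicle recycling, Itsn1, a scaffold of endocytosis, Kcnj6, a potassium channel, and the adhesion molecules Dscam and Ncam2 rose as well. Olig1 and Olig2, transcription factors of the oligodendrocyte lineage, did not pass the test.

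In Dp16 against WT, edgeR called 62 of the 122 tested segment genes, all of them higher, or 50.8%, against 0.212% of genes outside the segment. Among the 101 segment genes with at least 1 CPM the median log2 fold change was 0.56 (interquartile range 0.45 to 0.65), and 99 were positive. Per mouse, the median log2 ratio to the WT mean was 0.56 ± 0.0130 (SD, n = 6) in Dp16 and 0.00223 ± 0.0199 (n = 6) in WT (two-sided exact permutation p = 0.00216, the smallest these groups allow). App rose by 0.63 (edgeR adjusted p = 1.37e-07), from 1753 to 2719 CPM, Dyrk1a by 0.59 (edgeR adjusted p = 1.18e-07) and Sod1 by 0.46 (edgeR adjusted p = 0.000128). Rcan1 rose by 0.60, Synj1 by 0.72, Itsn1 by 0.53 and Kcnj6 by 0.77. The ubiquitin ligase Ttc3 rose by 0.65, the transcription factor Ets2 by 0.54, the deubiquitinase Usp16 by 0.47, Dscam by 0.69 and Ncam2 by 0.83. Log2 fold changes of 0.35 for Olig1 (edgeR adjusted p = 0.0863), 0.30 for Olig2 (edgeR adjusted p = 0.481), 0.72 for the protease Bace2 (edgeR adjusted p = 0.302) and 0.45 for Runx1 (edgeR adjusted p = 0.478) did not pass. Among the segment genes with at least 1 CPM, the highest values were those of Ripk4 with 1.18 and Mx2 with 0.81, neither of which passed, and of Ncam2 between them, and the lowest those of C130023A14Rik with 0.06, Lca5l with -0.03 and Gm9843 with -0.16. Tested against 1.5-fold, 2 genes departed from the copy ratio, both below it: the predicted genes Gm9843 and Gm49708 (log2 fold change -0.70), each with an adjusted p = 0.00951 over the segment alone in edgeR.

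In Dp16_2xIFNRs against WT, edgeR called 66 segment genes, all higher, and 56 of them were also called in Dp16 against WT. The median log2 fold change was 0.55, or 1.46-fold, and 95 of the 101 genes were positive. Per mouse it was 0.54 ± 0.0123 (SD, n = 5), apart from WT (two-sided exact permutation p = 0.00216, the smallest these groups allow) and lower than in Dp16 by a difference of -0.0187 (exact permutation p = 0.0455). The 4 receptor genes are part of this summary, and over the other 97 genes the difference was 0.00504 (exact permutation p = 0.671). App rose by 0.56 (edgeR adjusted p = 9.32e-07), Dyrk1a by 0.53 (edgeR adjusted p = 7.28e-07) and Sod1 by 0.41 (edgeR adjusted p = 0.00114). Mx2, an interferon-induced GTPase encoded in the segment, rose by 1.13 (edgeR adjusted p = 0.0476), a call that leaving out each of 11 libraries ended (highest adjusted p = 0.194, without Dp16_2xIFNRs replicate 3).

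**Figure D2:**
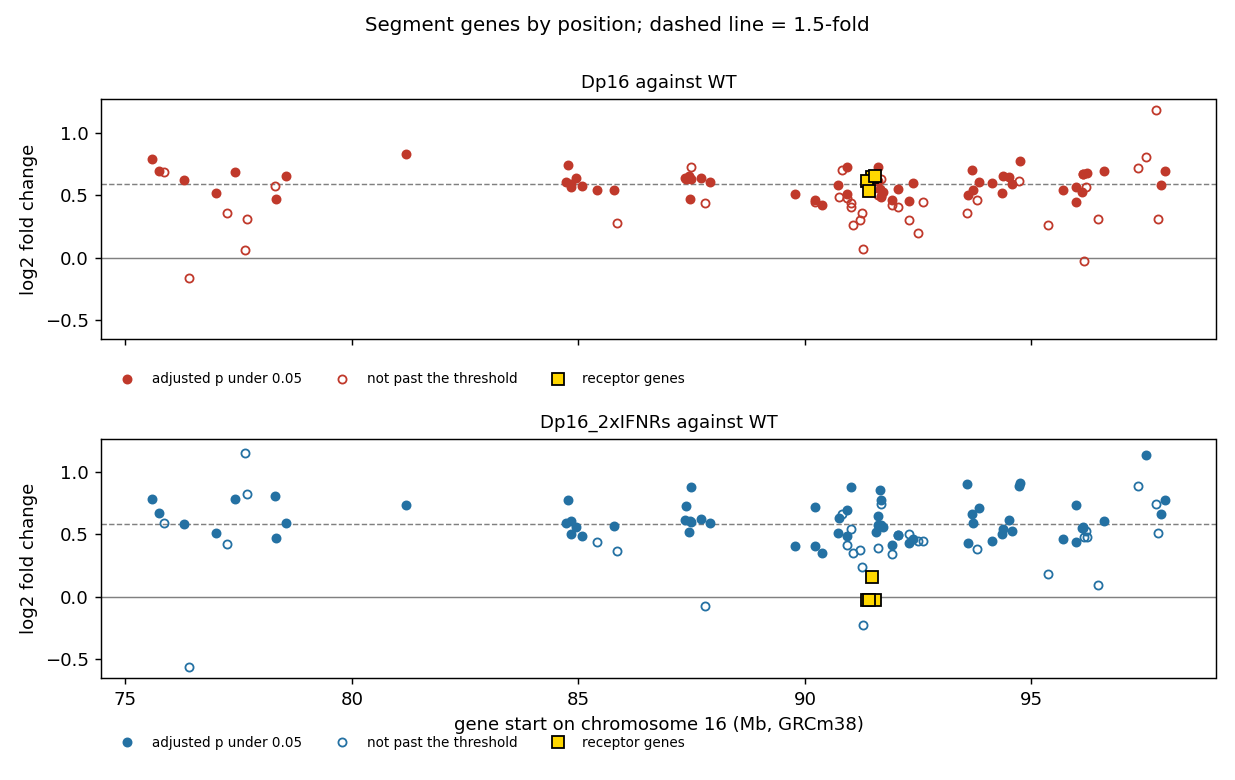
Log2 fold change against WT of segment genes by gene start on chromosome 16 in megabases, for Dp16 and for Dp16_2xIFNRs (filled points edgeR adjusted p under 0.05, open points above it, gold squares the 4 receptor genes, dashed line 1.5-fold). In Dp16 the receptors lie at 0.54 to 0.65 among their neighbours, and in Dp16_2xIFNRs they lie at -0.02 to 0.16 while Tmem50b and Gart beside them stay near the dashed line.

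The third comparison asked what else differed between Dp16 and WT hippocampus. Outside the segment few genes changed, and most of those rose. Cbs, the enzyme that makes cystathionine from homocysteine, fell, as did Tnc, the matrix protein tenascin C, and Mfge8, a secreted protein that bridges dying cells to phagocytes. C4b, a complement component, rose, with Lyz2, a lysozyme of myeloid cells, Cybrd1, a ferric reductase, and Slc5a5, the sodium-iodide symporter. Interferon-stimulated genes were called higher as a group by camera, but not with the correlation between genes estimated (adjusted p = 0.497 with an estimated correlation), and no single member passed the test across all genes.

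EdgeR called 40 genes outside the segment, 25 higher and 15 lower, 6 of them without a full name and 1 on chromosome 16. At an unadjusted p under 0.05 there were 1724, where 949 would be reached by chance. The count fell to 24 without WT replicate 3. The largest fold change among the called genes was that of a, the agouti signalling protein of the hair follicle (ENSMUSG00000027596.10, chromosome 2, 154791402 to 155051012). It had 3 counts over the 6 WT libraries and 512 over the 6 Dp16 libraries, a ratio of 172 (95% Clopper-Pearson interval 58.5 to 836). In the 5 Dp16_2xIFNRs libraries it had 384 counts, a ratio of 157 (53.3 to 765). Its level was 2.68 CPM in Dp16 and 2.45 CPM in Dp16_2xIFNRs.

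Slc5a5 rose by 0.73 on the log2 scale (edgeR adjusted p = 8.95e-05), from 19.9 to 32.8 CPM. C4b rose by 0.68 ± 0.10 (SE; edgeR adjusted p = 0.000926), from 35.7 to 57.1 CPM. Further rises were those of Selenov, a selenoprotein, by 1.88, Slc25a34, a mitochondrial carrier, by 0.92, the histone H2ac6 by 0.84, the transcription factor Tfcp2l1 by 0.75, Cybrd1 by 0.71 and Rida, an imine deaminase, by 0.50 (highest of these edgeR adjusted p values 0.00213). Lyz2 rose by 0.60 (edgeR adjusted p = 0.0230), a call that leaving out each of 7 libraries ended (highest adjusted p = 0.0719, without WT replicate 1). Cbs fell by 0.59 ± 0.06 (SE; edgeR adjusted p = 1.47e-05), from 27.1 to 18.0 CPM, and lay lower in all Dp16 mice than in all WT mice. Tnc fell by 0.69 (edgeR adjusted p = 0.00517), Mfge8 by 0.38 (edgeR adjusted p = 0.0117), Rec8, a meiotic cohesin, by 1.42 (edgeR adjusted p = 0.00512) and Rfx5, a regulator of MHC class II genes, by 0.50 (edgeR adjusted p = 0.0048). Pik3r3, a regulatory subunit of phosphoinositide 3-kinase, fell by 0.31 and the tetraspanin Tspan17 by 0.26. Grin2c, a subunit of the NMDA receptor, fell by 0.40 (edgeR adjusted p = 0.0307), a call that leaving out each of 8 libraries ended (highest adjusted p = 0.0974, without Dp16 replicate 5). Dyrk1b, a kinase related to Dyrk1a, fell by 0.32 (edgeR adjusted p = 0.0364), which each of 12 ended (highest 0.109, without WT replicate 1). Pnrc1, a nuclear receptor coactivator, fell by 0.30 (edgeR adjusted p = 0.0448), which each of 14 ended (highest 0.129, without WT replicate 3). The identifier series as a covariate ended the calls of Mfge8, Rec8, Rfx5, Tspan17, Lyz2, Grin2c, Dyrk1b and Pnrc1, and the length slope those of Mfge8, Rec8, Pik3r3, Tspan17, Grin2c, Dyrk1b and Pnrc1. With the series in the model fewer Dp16 mice are compared, so a call lost with it does not tell a batch from a smaller group. Over 19 alternatives the highest edgeR adjusted p was 0.0514 for Rfx5, 0.0560 for Rec8, 0.0616 for Pik3r3, 0.0910 for Mfge8 and 0.132 for Tspan17. Without the 3 libraries low in choroid plexus, Dyrk1b, Mfge8, Pnrc1 and Tspan17 were not.

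**Figure D3:**
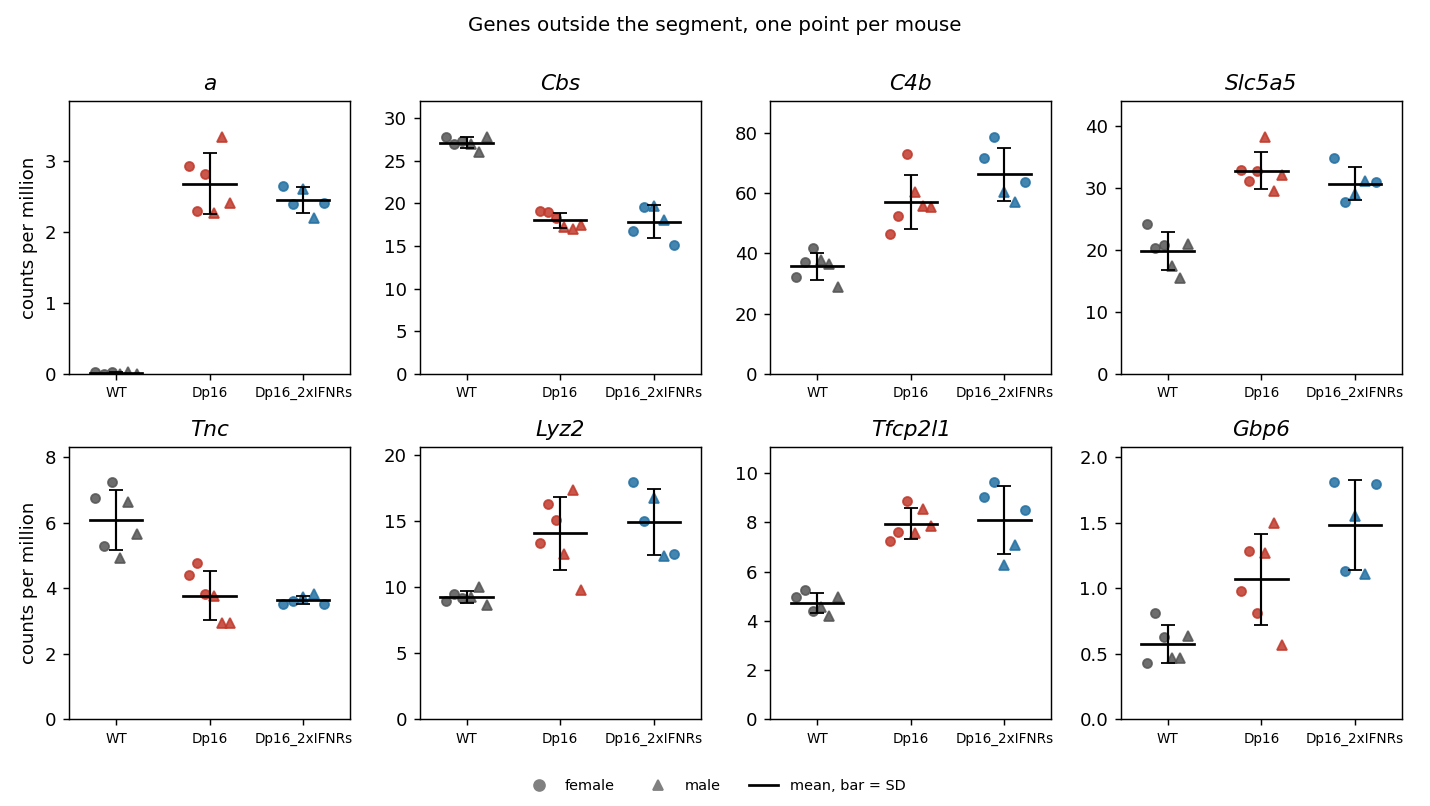
Expression in CPM of a, Cbs, C4b, Slc5a5, Tnc, Lyz2, Tfcp2l1 and Gbp6 for each mouse of the WT, Dp16 and Dp16_2xIFNRs groups (circles females, triangles males, black line the mean, bar 1 SD). Cbs has means of 27.1, 18.0 and 17.8 CPM and C4b of 35.7, 57.1 and 66.2 CPM in that order.

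Of the 47 lists, camera called 14 in Dp16 against WT, 12 higher and 2 lower; with an estimated correlation the receptor list alone was called (adjusted p = 0.00152). Interferon-stimulated genes had a median log2 fold change of 0.25, with 43 of 46 positive (camera adjusted p = 2.32e-09; adjusted p = 0.497 with an estimated correlation). EdgeR called 0 of them over all genes and 0 adjusted over the list alone, with 14 higher at an unadjusted p under 0.05 and 0 called by DESeq2 or limma-voom. Dhx58, a cytosolic RNA sensor of the list, had a log2 fold change of 0.57 (edgeR adjusted p = 0.304). The list's level lay above the WT mean in 6 of 6 Dp16 mice (exact permutation p = 0.0693; 0.326 adjusted over the lists). Genes of the interferon gamma response had a median of 0.20, with 21 of 25 positive and 1 member higher when adjusted over the list alone (camera adjusted p = 0.00161; adjusted p = 0.644 with an estimated correlation).

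Reactive astrocyte genes had a median of 0.19, with 19 of 22 positive (camera adjusted p = 0.00161; adjusted p = 0.0699 with an estimated correlation; fry adjusted p = 0.00684). C4b was the member called over all genes, and 3 rose and 1 fell when adjusted over the list alone. Genes of GABAergic interneurons, the inhibitory neurons, had a median of 0.11, with 24 of 27 positive (camera adjusted p = 3.28e-06; adjusted p = 0.497 with an estimated correlation). The member called was Dlx6os1, an antisense RNA of the Dlx5 and Dlx6 locus, with 0.50 (edgeR adjusted p = 0.0181), a call that leaving out each of 3 libraries ended (highest 0.0644, without WT replicate 3), as did the identifier series (0.191). Clustered protocadherins, adhesion molecules of neurons, had a median of 0.11 with 42 of 57 positive (camera adjusted p = 0.000236; adjusted p = 0.498 with an estimated correlation). Genes of cholesterol synthesis had a median of 0.07 with 21 of 24 positive (camera adjusted p = 0.0018; adjusted p = 0.644 with an estimated correlation), among them Hmgcs1 with 0.29 (edgeR adjusted p = 0.106). Cytosolic ribosomal proteins stood lower, with a median of -0.14 and 0 of 79 positive (camera adjusted p = 1.75e-15; adjusted p = 0.644 with an estimated correlation). Dp16 replicate 4 stood apart in the mean level of this list, at -0.46 (other Dp16 mice -0.163 to 0.0122). Leaving out each library gave medians of -0.188 to -0.0859, and camera called the list each time. Subunits of oxidative phosphorylation had a median of -0.08 with 9 of 71 positive (camera adjusted p = 1.18e-06; adjusted p = 0.681 with an estimated correlation). With the length slope as a covariate the ribosomal list was not called (median -0.02, camera adjusted p = 0.0900), nor was the oxidative phosphorylation list (adjusted p = 0.890).

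The calls of 5 immune lists were lost when some single libraries were left out, while their medians stayed positive in every such fit. Complement genes had a median of 0.05 with 14 of 18 positive (camera adjusted p = 0.0116; adjusted p = 0.586 with an estimated correlation), not called without WT replicate 6 (0.0721). Peripheral leukocyte genes had a median of 0.71 with 6 of 7 positive (camera adjusted p = 0.0116; adjusted p = 0.497 with an estimated correlation), not called without Dp16 replicate 3 (0.0611) or WT replicate 1 (0.0532). Cytokines and chemokines had a median of 0.11 with 15 of 19 positive (camera adjusted p = 0.0217; adjusted p = 0.497 with an estimated correlation), not called without WT replicate 2 (0.0747) or WT replicate 6 (0.0726). MHC class I genes had a median of 0.16 with 16 of 20 positive (camera adjusted p = 0.0283; adjusted p = 0.681 with an estimated correlation), a call that leaving out each of 5 libraries ended (highest 0.217, without Dp16 replicate 5). MHC class II genes had a median of 0.33 with 9 of 9 positive (camera adjusted p = 0.0412; adjusted p = 0.644 with an estimated correlation), a call that each of 8 ended (highest 0.131, without WT replicate 6). The identifier series as a covariate, which leaves fewer Dp16 mice to compare, ended the calls of MHC class I genes (0.0721), cytokines (0.0721) and interferon gamma response genes (0.0545).

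The fourth comparison asked what differed from WT when the duplication was present and the receptors were at normal dosage. Most genes called in Dp16 were called here too: C4b and Slc5a5 rose, and Cbs, Tnc and Mfge8 fell. Further genes rose, among them Gbp6, an interferon-inducible GTPase, C2, a complement component, Cybb, the catalytic subunit of the phagocyte NADPH oxidase, and Lrp2, an endocytic receptor of epithelia. The calls of C2, Cybb and Lrp2 rested on single libraries. Chrdl1, an antagonist of bone morphogenetic proteins made by astrocytes, and Sall3, a transcription factor, fell. Camera called genes of the interferon gamma response higher as a group, and those of ribosomes and mitochondrial respiration lower. None of these calls held with the correlation between genes estimated (adjusted p = 0.563, 0.563 and 0.603 with an estimated correlation).

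EdgeR called 120 genes outside the segment, 55 higher and 65 lower, with 3143 at an unadjusted p under 0.05. Of the 120, 13 had no full name and 1 lay on chromosome 16. The count of 120 changed with the library left out. It was 449 without Dp16_2xIFNRs replicate 1, 60 without replicate 2, 45 without replicate 3 and 68 without replicate 4 of that group. It was 75 without WT replicate 1, 183 without WT replicate 2, 74 without WT replicate 3, 364 without WT replicate 4 and 73 without WT replicate 5. Of the 40 genes called in Dp16 against WT, 32 were called here in the same direction. Both comparisons use the same WT mice, so this sharing is not independent evidence. With no change simulated, 36.4 of the 40 top genes had the same sign in both on average (7 to 40), as 40 of 40 did in the data. In the same simulation 6.87 of the 40 were also top genes of the other comparison on average (0 to 39), against 31 in the data. With 3 WT mice for one comparison and the other 3 for the other, an average of 9.5 genes were shared (4 to 13 over 20 such divisions), where 0.126 would be if the calls were independent. With the same 3 WT mice for both, 23.6 were shared (6 to 132).

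Cbs fell by 0.61 (edgeR adjusted p = 2.89e-05), to 17.8 CPM, and C4b rose by 0.88 (edgeR adjusted p = 8.74e-05), to 66.2 CPM. Tnc fell by 0.75 (edgeR adjusted p = 0.00381) and Mfge8 by 0.56 (edgeR adjusted p = 0.000292). Slc5a5 rose by 0.62 (edgeR adjusted p = 0.00107), Tfcp2l1 by 0.76, Selenov by 1.94 and H2ac6 by 0.79. Gbp6 rose by 1.35 (edgeR adjusted p = 0.0103), Fgl2, a fibrinogen-like protein of immune cells, by 0.90 (edgeR adjusted p = 0.0132), Slc6a12, a transporter of betaine and GABA, by 1.53 (edgeR adjusted p = 0.0125) and the linker histone H1f4 by 1.38 (edgeR adjusted p = 0.0110). Sall3 fell by 0.74 (edgeR adjusted p = 0.00122), Chrdl1 by 0.77 (edgeR adjusted p = 0.00708) and Fgfr3, a growth factor receptor of astrocytes, by 0.35 (edgeR adjusted p = 0.00251). Of 35 named genes called here, 24 stayed called whichever library was left out. The other 11 lost the call without some libraries, with the highest adjusted p as follows: Lrp2 (rise of 1.23) 0.0642 without Dp16_2xIFNRs replicate 2, Slc47a1 (2.00), a transporter of organic cations, 0.108 without replicate 4, C2 (0.96) 0.144 without replicate 4, and Cybb (0.94) 0.160 without replicate 3 of the same group. Among the falls these were Mlph (-0.91) with 0.151, Egfl6 (-0.59) with 0.123, the apoptosis gene Bbc3 (-0.56) with 0.139 and Rec8 (-1.21) with 0.109, each without Dp16_2xIFNRs replicate 3, and Entpd2 (-0.57), an ectonucleotidase, with 0.0861 without replicate 2. Lyz2 (0.68) reached 0.0590 without Dp16_2xIFNRs replicate 3, and the eleventh was Mx2 of the segment. Of the 17 fits without a library, C2 lost the call in 12, Mlph in 8 and Cybb in 7. Fgl2 was not called with only the 2 groups compared (edgeR adjusted p = 0.0534; 0.000121 to 0.0534 over 19 alternatives), with the replicate block or without the 3 libraries low in choroid plexus.

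Camera called 14 lists in Dp16_2xIFNRs against WT, 7 higher and 7 lower, and 0 with an estimated correlation (fry called 1, the reactive astrocytes). Genes of the interferon gamma response had a median log2 fold change of 0.45, with 21 of 25 positive, 2 called over all genes, and 16 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.14e-08; adjusted p = 0.563 with an estimated correlation). The 2 were Gbp6 and Gbp9, the latter with 0.57 (edgeR adjusted p = 0.0169) and not called without Dp16_2xIFNRs replicate 3 (0.0797) or replicate 4 (0.0597). With the replicate block neither was called (0.0588 for Gbp6 and 0.0671 for Gbp9). Interferon-stimulated genes had a median of 0.28 with 42 of 46 positive and 3 higher adjusted over the list alone (camera adjusted p = 5.03e-07; adjusted p = 0.563 with an estimated correlation). Ifit1 had 0.69 (edgeR adjusted p = 0.0922) and Samd9l 0.48 (edgeR adjusted p = 0.0968). MHC class II genes had a median of 0.62 with 8 of 9 positive (camera adjusted p = 0.00445; adjusted p = 0.563 with an estimated correlation), not called without Dp16_2xIFNRs replicate 1 (0.0570), and the invariant chain Cd74 had 0.94 (edgeR adjusted p = 0.146). MHC class I genes had a median of 0.23 (camera adjusted p = 0.00445; adjusted p = 0.774 with an estimated correlation), not called without that library either (0.147). Complement genes had a median of 0.21 with 12 of 18 positive (camera adjusted p = 0.00417; adjusted p = 0.563 with an estimated correlation). Reactive astrocyte genes had a median of 0.20 with 18 of 22 positive (camera adjusted p = 0.000673; adjusted p = 0.0808 with an estimated correlation; fry adjusted p = 0.00132). Markers of meningeal and perivascular fibroblasts, cells of the brain's coverings, moved with these lists: their median was 0.55 with 18 of 20 positive (camera adjusted p = 3.53e-05; adjusted p = 0.652 with an estimated correlation), with 0.68 for the collagen Col1a1 and 0.90 for Aldh1a2.

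Ribosomal protein genes had a median of -0.23 with 0 of 79 positive and 60 lower adjusted over the list alone (camera adjusted p = 9.64e-24; adjusted p = 0.563 with an estimated correlation). Subunits of oxidative phosphorylation had a median of -0.16 with 0 of 71 positive (camera adjusted p = 2.68e-16; adjusted p = 0.603 with an estimated correlation). Genes of adult neurogenesis had a median of -0.17 with 5 of 24 positive (camera adjusted p = 0.00738; adjusted p = 0.563 with an estimated correlation). Their called member was Marcksl1, a regulator of actin, with -0.38 (edgeR adjusted p = 0.0108), a call lost without Dp16_2xIFNRs replicate 3 (0.0503). Astrocyte markers had a median of -0.08 with 7 of 22 positive (camera adjusted p = 0.00738; adjusted p = 0.774 with an estimated correlation), not called without Dp16_2xIFNRs replicate 3 (0.102).

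**Figure D4:**
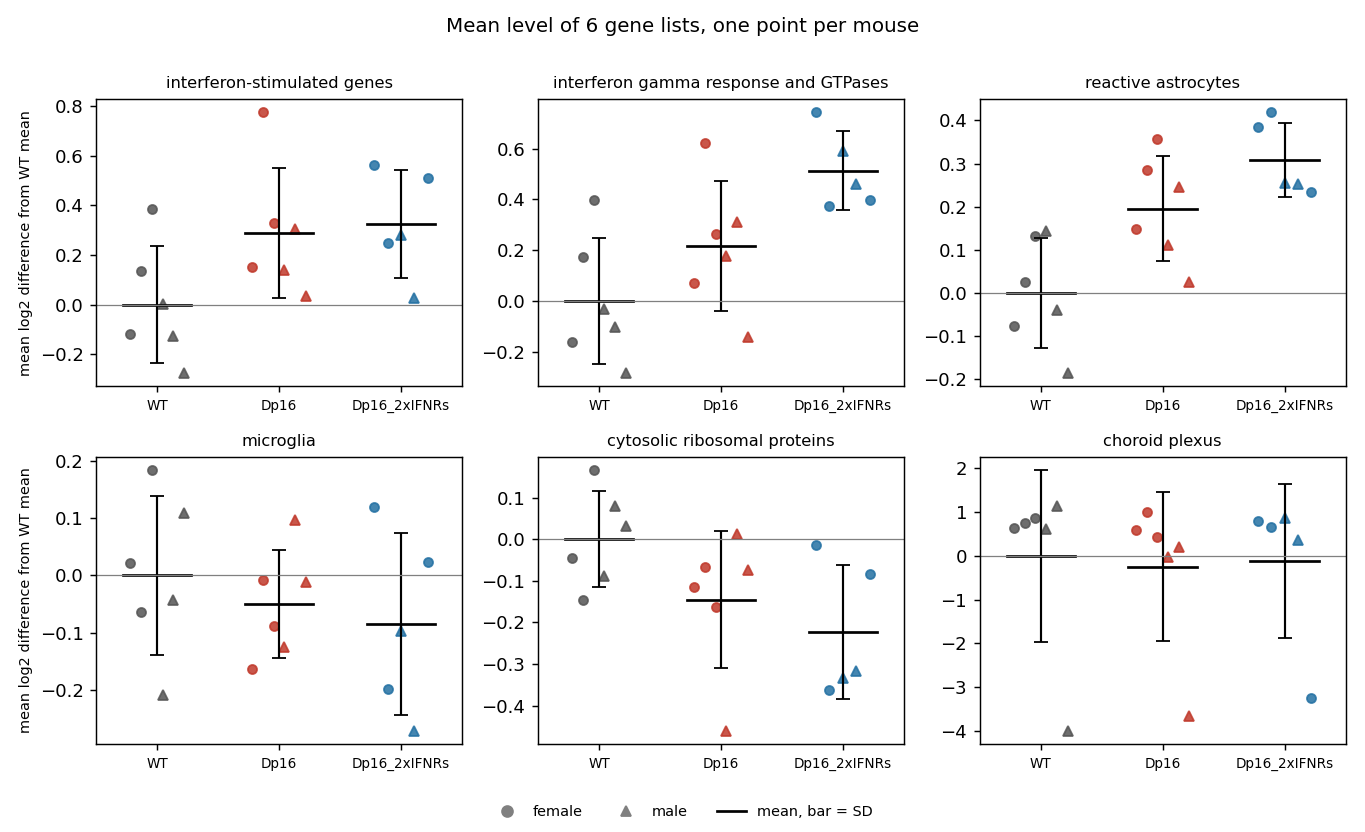
Mean log2 difference from the WT mean over the genes of 6 lists (interferon-stimulated, interferon gamma response, reactive astrocytes, microglia, ribosomal proteins, choroid plexus) for each mouse of the WT, Dp16 and Dp16_2xIFNRs groups (circles females, triangles males, black line the mean, bar 1 SD). The interferon-stimulated level lies above the WT mean in 6 of 6 Dp16 and 5 of 5 Dp16_2xIFNRs mice, and 1 mouse of each group lies far below the others in choroid plexus level (-4.00, -3.66 and -3.24).

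The fifth comparison, Dp16_2xIFNRs against Dp16, asked what the receptor dosage changed on the background of the duplication. Ifnar1, Ifnar2 and Ifngr2 fell, and edgeR called no other gene. C4b, Cbs and Slc5a5 were not called and stood at 66.2, 17.8 and 30.7 CPM in Dp16_2xIFNRs, against 57.1, 18.0 and 32.8 CPM in Dp16. Camera called genes of the interferon gamma response and of meningeal fibroblasts higher in Dp16_2xIFNRs, and ribosomal and respiratory genes lower. None of these calls held with the correlation between genes estimated (adjusted p = 0.774, 0.860, 0.907 and 0.907 with an estimated correlation).

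Other than the receptors, edgeR called 0 genes, with 1982 at an unadjusted p under 0.05; DESeq2 called 2, edgeR without a filter 10, and limma-voom 0. The count was 1 without Dp16_2xIFNRs replicate 1. Simulated changes of 1.5-fold were recovered in 70.1% of genes in this comparison, and the smallest simulated changes in 29.9%. The many changed genes of the simulation loosen its adjusted threshold, and the real comparison had few calls. These shares can therefore overstate what the real comparison could detect, where Il10rb did not pass (edgeR adjusted p = 0.277). Camera called 14 lists, 2 higher and 12 lower, of which the receptors alone were called with an estimated correlation (median -0.60, adjusted p = 0.00201 with it). Interferon-stimulated genes had a median log2 fold change of -0.02 with 20 of 46 positive (camera adjusted p = 0.823; exact permutation p = 0.818 per mouse). Interferon gamma response genes had a median of 0.22 with 23 of 25 positive (camera adjusted p = 7.98e-05; adjusted p = 0.774 with an estimated correlation; exact permutation p = 0.0498 per mouse, 0.390 adjusted over the lists). Meningeal and perivascular fibroblast markers had a median of 0.28 with 20 of 20 positive (camera adjusted p = 0.000683; adjusted p = 0.860 with an estimated correlation). Oxidative phosphorylation genes had a median of -0.07 (camera adjusted p = 3.57e-06; adjusted p = 0.907 with an estimated correlation) and ribosomal genes of -0.09 (camera adjusted p = 4.42e-05; adjusted p = 0.907 with an estimated correlation). GABAergic interneuron genes had a median of -0.11 (camera adjusted p = 0.000727; adjusted p = 0.774 with an estimated correlation), and genes of synaptic vesicle release of -0.07 (camera adjusted p = 0.00275; adjusted p = 0.860 with an estimated correlation). Genes of adult neurogenesis had a median of -0.14 (camera adjusted p = 0.00546; adjusted p = 0.774 with an estimated correlation).

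The share of the Dp16 change that was absent at normal receptor dosage was estimated over the 100 genes outside the segment ranked highest in 3 of the 6 Dp16 mice. In the other Dp16 mice their median signed log2 difference from WT averaged 0.153 over 20 splits (0.103 to 0.215), and in Dp16_2xIFNRs it averaged 0.202 (0.0624 to 0.322). The share absent was therefore -31.6% (SD 50.7 between splits), and Dp16_2xIFNRs lay below the other Dp16 mice in 7 of 20 splits. The splits reuse the same mice, and every split holds all Dp16_2xIFNRs mice. Neither the SD nor the 7 of 20 therefore measures the sampling error of the share. With no simulated change the same averages were 0.00160 and 0.00585. The simulated genes were drawn independently of each other. These averages therefore do not show how far genes that vary together between mice would move them.

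The last comparison asked whether the effect of the duplication differed between females and males. Neither the receptors, App, Cbs and C4b nor any other gene had a sex-dependent effect that passed. EdgeR called 0 genes for the interaction of sex and Dp16 (566 at an unadjusted p under 0.05, where 949 would be reached by chance; DESeq2 called 0, with 531 unadjusted), and 1 without WT replicate 6. The genes with the smallest p values included Coq6, an enzyme of ubiquinone synthesis, with an interaction of -0.60, and the somatostatin receptor Sstr3 with 0.49, each with an edgeR adjusted p of 1.00. Simulated interactions of 2-fold were recovered in 54.5% of genes, and those of 1.5-fold in 19.4%. The many changed genes of that simulation loosen its adjusted threshold, so these shares can overstate what the real test could detect.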

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

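No explanation was tested for the values in this part; the test for a library that stands apart from its group was planned. It found such a library in 16 of 261 groups of values, and about 13.05 groups would have one by chance at 1 in 20. Some libraries, such as WT replicates 4 and 6, stood apart in several of these groups.

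Among the receptors, Ifnar1 was at 48.3 CPM in WT replicate 2 (other WT mice 39.1 to 42.4), and Il10rb at 8.47 CPM in Dp16 replicate 6 (other Dp16 mice 11.6 to 13.1). Rec8 was at 2.49 CPM (others of the group 0.994 to 1.40) and Bbc3 at 7.27 CPM (others 4.86 to 5.45) in Dp16_2xIFNRs replicate 2.

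Levels of lists are mean log2 differences from the WT mean. Choroid plexus markers, of a tissue inside the ventricles, were far below the group in WT replicate 6 at -4.00 (others 0.61 to 1.14), in Dp16 replicate 6 at -3.66 (others -0.0191 to 1.00) and in Dp16_2xIFNRs replicate 5 at -3.24 (others 0.35 to 0.85). WT replicate 4 was high in markers of thalamus and habenula at 1.30 (others -0.596 to 0.0311) and of pericytes and smooth muscle at 0.39 (others -0.196 to 0.00522), and low in those of adult neurogenesis at -0.13 (others -0.00571 to 0.0545). WT replicate 6 was low in complement genes at -0.41 (others 0.0359 to 0.162) and high in genes of synaptic vesicle release at 0.12 (others -0.0445 to -0.00634). WT replicate 3 was high in MHC class I genes at 0.35 (others -0.0923 to -0.0496). Dp16 replicate 4 was low in ribosomal protein genes at -0.46 (others -0.163 to 0.0122). Dp16_2xIFNRs replicate 1 was high in cytokines and chemokines at 0.40 (others -0.0204 to 0.0891) and in genes of disease-associated microglia at 0.36 (others -0.0221 to 0.0855).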

How the results depend on the processing

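The choroid plexus covariate, the length slope covariate, both covariates together, the fit without 3 libraries and limma-voom with the identifier code as a block were chosen after seeing the data; the other alternatives were planned. The receptor counts, the 62 and 66 segment calls, the 2 genes departing from 1.5-fold, the count of 0 sex interactions and the share absent stayed within 1.5 times or 1 SD of their values under every alternative but those named here. Leaving out each library gave 3 to 4 called receptors in Dp16 against WT and in Dp16_2xIFNRs against Dp16, and 0 to 1 in Dp16_2xIFNRs against WT. Segment calls ranged from 57 to 66 in Dp16 and from 56 to 69 in Dp16_2xIFNRs, the median segment log2 fold change from 0.53 to 0.58, departures from 2 to 2, and sex interactions from 0 to 1. Genes outside the segment ranged from 24 to 51 in Dp16 and from 45 to 449 in Dp16_2xIFNRs, and those other than the receptors in Dp16_2xIFNRs against Dp16 from 0 to 1. Called lists ranged from 12 to 21 in Dp16 against WT, from 11 to 16 in Dp16_2xIFNRs against WT and from 11 to 17 in Dp16_2xIFNRs against Dp16.

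Outside the segment, the 40 calls in Dp16 against WT became 141 with DESeq2, 84 at a threshold of 0.1, 76 with no filter, 16 with the identifier series and 18 with the length slope. The 120 in Dp16_2xIFNRs against WT became 557 with DESeq2, 404 at 0.1, 345 with no filter, 59 with only the 2 groups compared, 272 with a surrogate variable, 252 with the choroid plexus level and 78 with the length slope. Other than the receptors, Dp16_2xIFNRs against Dp16 gave 2 with DESeq2 and 10 with no filter. The looser threshold calls more by construction. The cause was not tested for the others, and the identifier series leaves fewer Dp16 mice to compare. Without the 3 libraries lowest in choroid plexus the counts were 35 and 98, with the replicate block 32 and 81, with the identifier code as a block 43 and 110, and with both covariates together 37 and 134. The median segment log2 fold change of 0.56 moved to 0.54 over all tested segment genes and on RPKM plus 0.1, 0.46 on RPKM plus 1, 0.55 with no covariate and 0.58 over the fixed list of segment genes. An added constant shrinks ratios of weak genes by construction.

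The 14 called lists of Dp16 against WT became 22 without the 3 libraries, 1 with an estimated correlation and 2 with fry. Those of Dp16_2xIFNRs against WT became 0 and 1, and those of Dp16_2xIFNRs against Dp16 1 and 2, with an estimated correlation and with fry. Between genes of the ribosomal list the estimated correlation was 0.866. Reversed values were the choroid plexus list in Dp16_2xIFNRs against Dp16, -0.39 with the replicate block in place of 0.22, and the ependymal list in Dp16 against WT, -0.147 without WT replicate 6 (leaving out each library gave -0.147 to 0.109, the highest without WT replicate 5). The ependymal list had a median of -0.0190 with all libraries, while the test pointed up. Neither list was called at the outset, and the cause was not tested. Of 366 values of named genes compared with DESeq2, 332 stayed on their side of the threshold and 34 passed it, and with TMM without the segment genes 369 of 369 stayed.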

Other observations

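In this part the tests of the skin, the single-library count and the engineered chromosome for a, of the difference between the duplication groups, of microglia, of genes that vary together and of the receptor dosage for interferon-stimulated genes, and of the genes of chromosomes 10 and 17 were chosen only after the result was seen. The skin test replaced an earlier form, the keratin sum itself (8.59 CPM with the duplication, 8.27 CPM in WT), which decided nothing because the brain expresses Krt10.

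Of the 47 lists, 23 were called in no comparison. In Dp16 against WT the markers of dentate gyrus granule cells had a median log2 fold change of -0.00362 (camera adjusted p = 0.711), those of CA1 pyramidal neurons of 0.08 (camera adjusted p = 0.0598), of CA2 and CA3 pyramidal neurons of -0.0137 (camera adjusted p = 0.988) and of mossy cells of -0.0853 (camera adjusted p = 0.379). Mature oligodendrocyte and myelin genes were at -0.04 (camera adjusted p = 0.674), endothelial genes at -0.02 (camera adjusted p = 0.790) and disease-associated microglia genes at -0.02 (camera adjusted p = 0.997). Immediate early genes, which report recent neuronal activity, were at -0.10 (camera adjusted p = 0.0690), glutamate receptors and postsynaptic genes at 0.05 (camera adjusted p = 0.0796) and GABA receptors at 0.02 (camera adjusted p = 0.658). Genes of the unfolded protein response were at -0.000159 (camera adjusted p = 0.326), heat shock proteins at 0.03 (camera adjusted p = 0.492), antioxidant targets of NRF2 at -0.00811 (camera adjusted p = 0.922) and JAK-STAT components at 0.04 (camera adjusted p = 0.341). Mitochondrially encoded genes were at -0.09 (camera adjusted p = 0.0852), with a level under the WT mean in every Dp16 mouse (difference -0.242, exact permutation p = 0.00649; 0.153 adjusted over the lists). Genes of cell proliferation were at -0.05 (camera adjusted p = 0.0761), with a level under it in every Dp16 mouse as well (difference -0.136, exact permutation p = 0.0152; 0.178 adjusted over the lists).

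Camera called some lists of brain regions next to the hippocampus, and none of these calls held with the correlation between genes estimated. In Dp16_2xIFNRs, thalamus and habenula genes had a median of -0.47 against WT (camera adjusted p = 0.0370; adjusted p = 0.841 with an estimated correlation). Without WT replicate 4, which was high in them, the median was -0.0543 (camera adjusted p = 0.550), and leaving out each of 5 libraries ended the call. Neocortex genes had a median of -0.23 against WT (camera adjusted p = 0.00498; adjusted p = 0.563 with an estimated correlation) and of -0.15 against Dp16 (camera adjusted p = 0.0156; adjusted p = 0.774 with an estimated correlation), the latter not called without Dp16_2xIFNRs replicate 3 (0.0830). Striatum genes had -0.15 against Dp16 (camera adjusted p = 0.0361; adjusted p = 0.860 with an estimated correlation), a call that leaving out each of 5 libraries ended (highest 0.195, without Dp16 replicate 3). Over all fits without 1 library the striatum median ran from -0.248 to -0.0388. Microglia markers had -0.06 in Dp16_2xIFNRs against WT (camera adjusted p = 0.0196; adjusted p = 0.841 with an estimated correlation), which each of 4 ended (highest 0.271, without Dp16_2xIFNRs replicate 4). The microglia median ran from -0.120 to -0.0253 in such fits. Against Dp16, blood genes had -0.35 (camera adjusted p = 0.00574; adjusted p = 0.774 with an estimated correlation; 0.0806 without Dp16_2xIFNRs replicate 4) and astrocyte markers -0.09 (camera adjusted p = 0.00656; adjusted p = 0.860 with an estimated correlation; 0.135 without replicate 3 and 0.0562 without replicate 4 of Dp16_2xIFNRs). Senescence and p53 targets had -0.08 (camera adjusted p = 0.0264; adjusted p = 0.268 with an estimated correlation; 0.105 without Dp16_2xIFNRs replicate 1), and clustered protocadherins -0.07 (camera adjusted p = 0.0361; adjusted p = 0.907 with an estimated correlation), which each of 3 ended (highest 0.235, without Dp16_2xIFNRs replicate 1).

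The gene a had counts in all mice with the duplication and nearly none in WT. Skin carried along is argued against by the keratin genes Krt5, Krt10, Krt14 and Krt15, of which the brain expresses Krt10: their sum exceeded WT by 0.323 ± 0.488 CPM (SE), against an excess of 2.56 CPM for a, and Krt14, abundant in skin, had 3 counts in all 11 duplication libraries. A change of the whole region is argued against by its neighbours, 15 genes within 500 kb. Their median log2 fold change was -0.012 in Dp16 against WT (range -0.35 to 0.16, 0 called). In Dp16_2xIFNRs against WT it was -0.062, and Necab3 was called there with a fall, not a rise (-0.46, edgeR adjusted p = 0.0368). A few libraries are argued against by the lowest count of 69 in 11 libraries. An agouti sequence carried by the engineered chromosome may account for the pattern and stays open: the highest WT count was 1, and an allele elsewhere in a separate colony would give the same counts, so the 2 cannot be told apart here. A strain difference at the locus and a biological effect of the duplication were not tested.

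The larger count of genes outside the segment in Dp16_2xIFNRs (120) than in Dp16 (40) was not ended by either technical covariate. With the length slope the count was 78, or 4.33 times the Dp16 count of the same fit, and with the choroid plexus level 252, or 4.27 times, which argues against both as the whole cause. A biological difference between the duplication groups stays open: of 88 genes called against WT in Dp16_2xIFNRs alone, 0 were called by edgeR in Dp16_2xIFNRs against Dp16, and 40 had an unadjusted p under 0.05 there. In Dp16 against WT, 88 of them had the same direction and 73 an unadjusted p under 0.05. The genes were picked by their calls in the same mice, so neither set of counts decides. The count could rest on structure among the mice, since it ranged from 45 to 449 with single libraries left out.

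Camera called interferon-stimulated genes higher in Dp16 against WT, a call lost with the correlation between genes estimated (adjusted p = 0.497 with an estimated correlation). A larger share of microglia is argued against by the microglia markers, with a median of -0.0363. The list stayed called in 12 of 12 fits without 1 library (median 0.16 to 0.33, highest camera adjusted p = 1.83e-05). These fits took the preset correlation between genes, so their calls cannot decide how far a single library carried the difference. The median stayed positive in each fit, while the list's level in the Dp16 mice ran from 0.0343 to 0.776. Members that vary together between mice may account for the call, given that adjusted p of 0.497. The third copy of the receptor genes as the biological cause stays open: the level per mouse in Dp16_2xIFNRs was not nearer to WT, but Dp16 itself was not apart from WT by the exact permutation test (p = 0.0693).

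Genes with counterparts on human chromosome 21 that lie on mouse chromosomes 10 and 17, outside the duplication, were tested as a set. Of 55 listed, 42 were tested, with a median log2 fold change of 0.00246 in Dp16 against WT and 23 positive. Called were Cbs in Dp16, and Cbs and Pcnt (-0.36, edgeR adjusted p = 0.0199), a protein of the centrosome, in Dp16_2xIFNRs. Whether they are called more often than other genes stayed undecided (Fisher exact p = 0.0854).

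Each count was compared with 100 of the 462 splits of the same mice into groups of these sizes (100 of 200 for the interaction). For the segment calls, 1 split, the real one, gave as many as 62 in Dp16 against WT (highest other 2). In Dp16_2xIFNRs against WT, 1 gave as many as 66 (highest other 31). The 3 receptors in Dp16_2xIFNRs against Dp16 were likewise reached by 1 split (highest other 0). This argues against chance for the segment and the receptors, as far as 100 splits can show, and sex was not balanced in the splits. The 40 genes outside the segment in Dp16 against WT were also reached by 1 split (highest other 4). That count is not on equal terms, since the segment calls of the real split loosen the adjusted threshold for all genes. For the 120 genes of Dp16_2xIFNRs against WT, 3 splits gave as many, and the highest other gave 2253, which points to a structure of the samples. On the second principal component (17.8% of the variance) Dp16_2xIFNRs replicate 1 lay at 9.38 and the other mice of its group at -17.0 to -11.7. Chance cannot be excluded for the numbers of called lists: 50 splits gave as many as the 14 in Dp16 against WT (highest other 23), 45 as the 14 in Dp16_2xIFNRs against WT (highest other 25) and 38 as the 14 in Dp16_2xIFNRs against Dp16 (highest other 23). Counts of 0 by edgeR, for genes other than the receptors in Dp16_2xIFNRs against Dp16 (1982 at an unadjusted p under 0.05, DESeq2 2, limma-voom 0) and for the sex interaction (566 unadjusted, DESeq2 0), were reached by 100 splits each (highest other 818 and 101). Any split reaches a count of 0 or more, so this was fixed in advance and says nothing about chance.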
